A study of Mus musculus with 8 samples.

How the data were processed

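Gene levels were FPKM values made by the authors with TopHat and Cufflinks on mm10, per the submitters' processing notes, and used as deposited. Versions of these tools and the annotation release were not given in the sources used here. Per the labels, total RNA was isolated with the RNeasy Plus Mini kit and libraries were made with NEBNext Ultra reagents. Each of the 8 files held 39009 entries with 38987 gene identifiers, FPKM, a status and the bounds of the 95% interval within the library. Of these entries 37451 were matched by identifier to GENCODE M21, 70.2% of them with the same coordinates and 99.8% overlapping, and the match gave biotypes and chromosomes. A spreadsheet had turned 27 symbols into dates, and these were restored from the identifiers. Entries marked LOWDATA (428, of which 40 reached FPKM 1) or FAIL (19) were left out, and none of 162 patch entries was tested.

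FPKM sums ran from 661114 to 771389. Depth was estimated from entries of low level on transcripts of at least 3000 bp, whose interval implies a whole number of fragments, up to 60 and within 0.02 of a whole number. Relative depth against ESC ran from 0.909 to 1.04. Mitochondrial transcripts held 1.94% (NSC-CiPSC line 2) to 11.6% (NSC) of the FPKM sum. Selenoprotein genes were inflated in all files, with 24 such genes holding 6.23% to 10.3% of the sum, and an implied length of 0.276 to 0.390 bp for Txnrd1 where other coding genes had medians of 1084 to 1222 bp. Levels of these genes are not interpreted, so the selenoprotein gene among the largest falls of the intestinal route is left out of the text.

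Genes with FPKM of at least 1 in at least 1 library were tested, 17011 in all, on log2(FPKM + 1). A linear model with 1 mean for each of 5 groups was fitted to all 8 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend (3 residual degrees of freedom, 1.10 prior). P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05 and at least 2-fold. A group with 1 library was assumed to vary like the CiPSC lines. The labels do not say whether the lines come from separate animals, so p-values measure the spread between these lines. In simulations with 100 genes changed 4-fold and 100 changed 16-fold, the share recovered was 71% to 90% at 4-fold and 93% to 100% at 16-fold, with 2 to 7 false calls. The simulations rest on the same assumption.

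Gene lists (26 lists, 406 genes, 16 in several lists, 4 not found in the files) were tested with camera in limma at a preset inter-gene correlation of 0.01 and with an estimated one, for lists with at least 5 tested members, adjusted over the lists of a comparison. None of the calls of these 26 lists held with the estimated correlation. That version of the test also uses only the 3 residual degrees of freedom, so a lost call need not reflect correlation between genes. In NSC-CiPSC against NSC the pluripotency list had an estimated correlation of -0.0161, below the preset. Its camera adjusted p still went from 1.18e-10 to 0.0883. Other lists had estimates far above the preset, such as glycolysis (0.891), 2-cell-like (0.610) and FGF and ERK target genes (0.357). For such lists the camera p-values at the preset correlation are likely too small. Counts adjusted over the list alone apply Benjamini-Hochberg to the p-values of its members. Overlaps are given beside the product of the list sizes divided by the genes tested. Residual source-cell expression was tested by an exact permutation of 5 lines, and NSC and IEC were compared by size alone.

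Named genes are the 6 largest rises and 6 largest falls among called genes with mean FPKM of at least 10 in the higher group, up to 4 members of each list with a call or at least 3 called members, and 19 identity genes. Of these, 18 are shown for every library in a figure (all but Xist), and the text gives some of them for only part of the libraries. Genes named Gm with digits, Rik, LOC, AK or BC, microRNAs, snoRNAs, Y-linked genes and Xist were left out of the largest changes, and not every gene the rule picks is printed. Genes named for residual expression, and those in the last part of the text, were chosen after their values were seen. The groups, tests, lists, thresholds, this rule and most alternatives were fixed before the data were examined. Leaving out marked entries, testing protein-coding genes without selenocysteine or genes outside X and Y alone, the share of source genes above ESC, and lists for exocrine and endocrine pancreas, liver, stomach and pancreatic mesenchyme, macrophages and the Xlr cluster were chosen after that. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.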

Results

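Gene expression was measured by RNA sequencing of total RNA in 8 mouse libraries that fall into 5 groups. Chemically induced pluripotent stem cells (CiPSC) are lines obtained from somatic cells with small-molecule compounds. There were 3 lines derived from neural stem cells (NSC-CiPSC lines 1, 2 and 3) and 2 lines derived from small intestinal epithelial cells (IEC-CiPSC lines 10 and 13). The controls were 1 library of cultured neural stem cells (NSC, passage 2), 1 library of primary small intestinal epithelial cells (IEC) and 1 library of R1 embryonic stem cells (ESC). Both somatic populations came from E13.5 embryos. Levels are given in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments). Depth estimated from the intervals in the files lay between 8.85 M fragments in NSC-CiPSC line 2 and 10.2 M in IEC-CiPSC line 13. Between 12547 genes (NSC-CiPSC line 1) and 14051 genes (IEC) reached FPKM 1. NSC, IEC and ESC have no replicates, so their levels carry no standard deviation (SD), and p-values rest on the spread between CiPSC lines of the same origin. Changes are differences of log2(FPKM + 1), which understate the change of genes with low levels.

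Pou5f1, Nanog, Zfp42 and Esrrb separated the somatic libraries from the pluripotent ones, while some other identity genes, such as Sox2, did not. Pou5f1, the core pluripotency transcription factor (chromosome 17, 35506018 to 35510776, mm10), was at FPKM 2.02 in NSC and 0.0810 in IEC. It reached 928 ± 76.7 (SD, n = 3) in NSC-CiPSC, 1189 ± 23.4 (SD, n = 2) in IEC-CiPSC and 1041 in ESC, where the interval in the file ran from 1022 to 1061. Nanog was at 0.455 in NSC and 0.157 in IEC against 348 ± 116, 555 ± 30.7 and 384 in NSC-CiPSC, IEC-CiPSC and ESC. Zfp42 was at 181 ± 50.01 in NSC-CiPSC, 227 ± 27.9 in IEC-CiPSC and 764 in ESC, and was listed at 0 in IEC and at 0.255 in NSC. Esrrb was at 126 ± 3.89, 161 ± 11.4 and 185 in the same 3 groups. Its log2 change was 5.25 from NSC to NSC-CiPSC and 7.27 from IEC to IEC-CiPSC. Klf4 was at 81.6 ± 10.6, 109 ± 2.63 and 75.4 in NSC-CiPSC, IEC-CiPSC and ESC, with 1.51 in NSC and 31.8 in IEC. Sox2, which neural stem cells share with pluripotent cells, was at 171 in NSC, 3.00 in IEC, 141 ± 3.13 in NSC-CiPSC, 232 ± 7.98 in IEC-CiPSC and 201 in ESC.

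Neural genes were high in the NSC library. Fabp7 was at 4546, Olig2 at 191, Nes at 49.8 and Pax6 at 21.9 in NSC. In the CiPSC lines Fabp7 lay between 0 (IEC-CiPSC line 13) and 5.78 (NSC-CiPSC line 2), Nes between 2.10 (IEC-CiPSC line 13) and 3.84 (NSC-CiPSC line 1), and Pax6 between 0 (IEC-CiPSC line 10) and 1.86 (NSC-CiPSC line 1). Olig2 was at 6.69 ± 3.91 in NSC-CiPSC and 8.07 ± 0.835 in IEC-CiPSC against 0.0436 in ESC. The epithelial adhesion genes Epcam and Cdh1 were at 15.9 and 11.9 in IEC, at 64.6 ± 4.05 and 79.3 ± 8.59 in NSC-CiPSC, at 63.9 ± 0.359 and 65.4 ± 2.82 in IEC-CiPSC, and at 38.9 and 88.0 in ESC. Cdx2, the intestinal master regulator, was at 0.0912 in IEC and at most 0.565 (NSC-CiPSC line 1) in any library, and Vil1, a brush border gene, was at 3.14 in IEC. Col1a1, a collagen of mesenchymal cells, was at 1873 in IEC. Gata6 was at 14.8 in IEC and below 1 in every other library. Sox17, an endoderm factor, was at most 0.658 (NSC-CiPSC line 2). The maternally expressed RNA Meg3 was at 0.805 in NSC, 349 in IEC, 200 ± 132 in NSC-CiPSC, 58.5 ± 4.23 in IEC-CiPSC and 149 in ESC. Xist, the RNA that coats the inactive X chromosome, was at 6.53 in NSC, 19.7 in IEC and 1.04 in ESC, and at 0.287 ± 0.124 in NSC-CiPSC and 0.453 ± 0.128 in IEC-CiPSC.

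**Figure D1:**
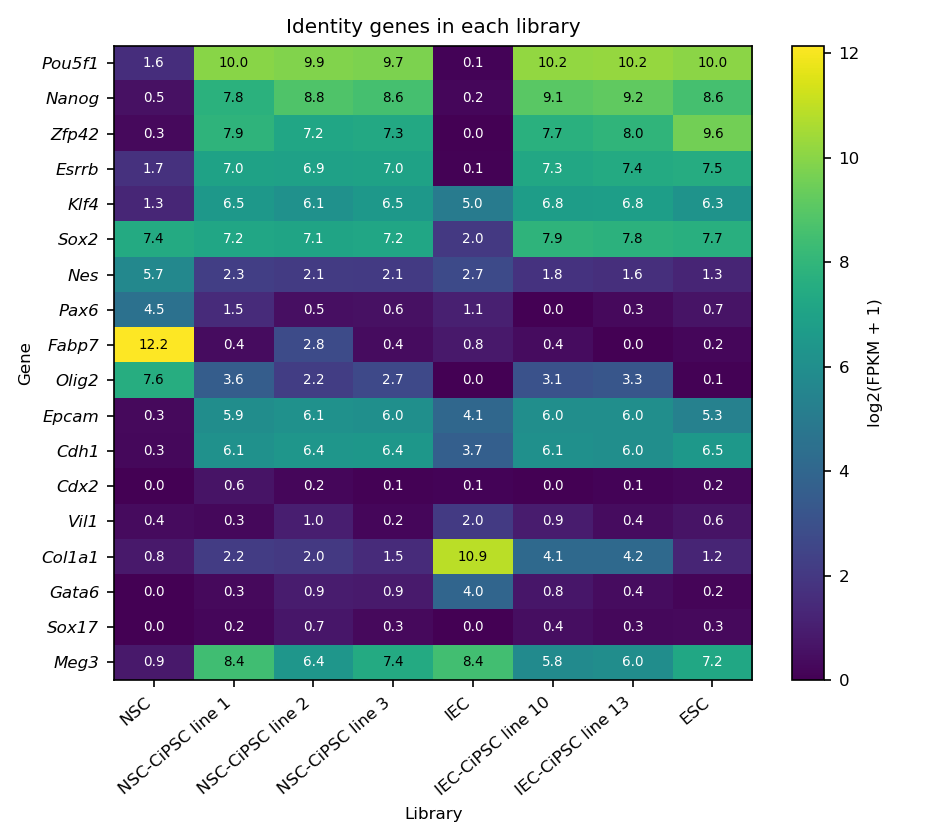
Level of 18 identity genes (rows) in each of the 8 libraries (columns), as log2(FPKM + 1), with the value in each cell. Pou5f1 is 9.7 or more in all 6 pluripotent libraries and 1.6 or less in NSC and IEC.

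The source populations were compared by size alone, since each is 1 library and the difference has no replicate check. Of all genes, 1290 differed at least 8-fold with FPKM of 5 or more in the higher library, 326 higher in NSC and 964 higher in IEC. Among the largest differences toward NSC were those of Fabp7 (11.31 on the log2 scale), Mt3, a brain metallothionein (9.69), and Ncan, a brain proteoglycan (9.41), together with Acsbg1 and Olig1, which were at 531 and 515 in NSC and listed at 0 in IEC. Toward IEC the largest differences were those of Afp and Alb, secreted hepatic proteins (NSC minus IEC -11.28 and -11.12), Col3a1 (-11.03), Lyz2, a lysozyme of macrophages (-10.83), the imprinted RNA H19 (-10.83) and Col1a2 (-10.51). In IEC, 18 of 20 fibroblast and mesenchyme genes, 8 of 10 smooth muscle genes and 10 of 12 leukocyte genes reached an FPKM of 10, with medians of 106, 124 and 81.2. By contrast 5 of 30 intestinal epithelium genes and 7 of 17 general epithelium genes did so, with medians of 1.52 and 6.62. Changes against IEC are therefore changes against a library that carried mesenchymal, smooth muscle, leukocyte, hepatic and pancreatic transcripts.

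**Figure D2:**
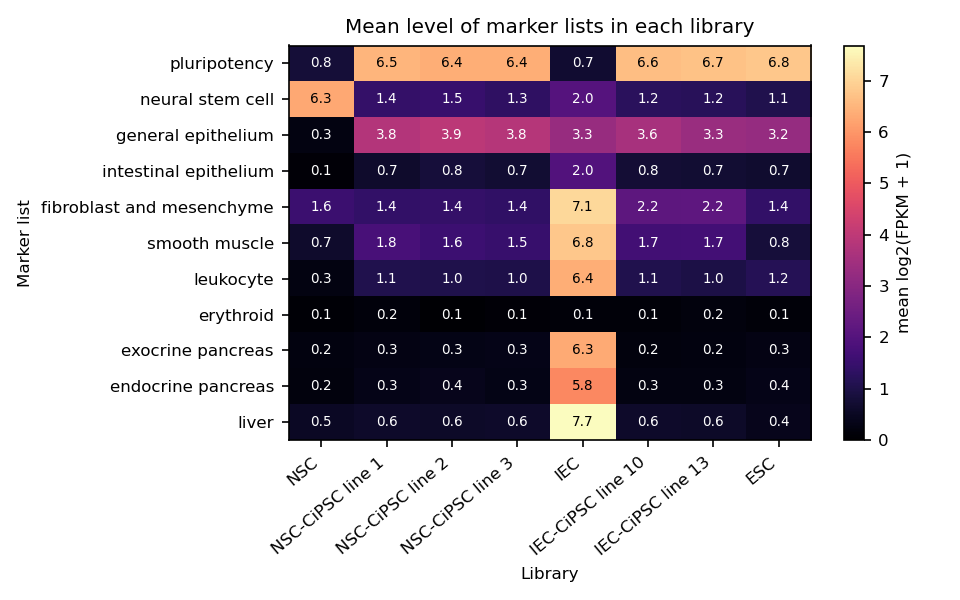
Mean log2(FPKM + 1) over the genes of 11 marker lists (rows) in each of the 8 libraries (columns), with the value in each cell; the pancreas and liver lists were written after the levels of several of their genes had been seen. In IEC the intestinal epithelium list averages 2.0 and the fibroblast and mesenchyme list 7.1.

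The comparison of NSC-CiPSC with NSC asks which genes differ between neural stem cells and the pluripotent lines made from them. Most pluripotency genes rose, and most neural stem cell and glial genes fell. The largest rises were those of Dppa5a (3545 ± 784 against 4.48, log2 change 9.31 ± 0.27 SE, adjusted p = 0.000120), Tdgf1, a growth factor co-receptor (8.43 ± 0.13, adjusted p = 2.26e-05), Mylpf, a myosin light chain (8.34 ± 0.11, adjusted p = 1.56e-05), Pou5f1 (8.26 ± 0.11, adjusted p = 1.60e-05), the small heat shock gene Hspb1 (7.91 ± 0.13, adjusted p = 2.65e-05) and Nanog (7.84 ± 0.44, adjusted p = 0.000576). The largest falls were those of Fabp7 (-10.96 ± 1.11, adjusted p = 0.00254), the growth factor Ptn (-9.20 ± 0.26, adjusted p = 0.000117), Sparcl1 (-8.64 ± 0.29, adjusted p = 0.000178), Ncan (-8.53 ± 0.30, adjusted p = 0.000189), the endothelin receptor Ednrb (-8.42 ± 0.19, adjusted p = 5.88e-05) and the membrane glycoprotein gene Gpm6b (-8.17 ± 0.25, adjusted p = 0.000138). All 12 moved the same way in 3 of 3 lines.

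Of 28 pluripotency genes, 27 rose (27 adjusted over the list alone, median log2 change 5.52, adjusted p = 1.18e-10). The gene that did not pass was Sox2 (log2 difference -0.27 ± 0.06 SE). Of 17 general epithelium genes, 15 rose (16 adjusted over the list alone, median 3.98, adjusted p = 5.84e-06), among them Cdh1 (6.05 ± 0.14), Cldn4, a tight junction gene listed at 0 in NSC and at 55.7 ± 9.16 in NSC-CiPSC, and Epcam (5.75 ± 0.09). Of 13 germline genes, 10 rose (10 adjusted over the list alone, median 3.03, adjusted p = 0.000514), led by the methyltransferase cofactor Dnmt3l (6.41 ± 0.72) and the meiosis gene Stra8 (5.89 ± 0.81). Of 10 tested genes of the 2-cell-like state, 9 rose (9 adjusted over the list alone, median 3.15, adjusted p = 0.00134), such as Zscan4f (5.73 ± 0.30) and Zscan4c (4.83 ± 0.28), members of a family of near-identical copies whose reads may be divided among them. With an estimated inter-gene correlation these lists had adjusted p = 0.0883 (pluripotency), 0.298 (general epithelium), 0.209 (germline) and 0.527 (2-cell-like).

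Of 24 neural stem cell genes, 22 fell (22 adjusted over the list alone, median -4.54, adjusted p = 6.68e-11), including the receptor phosphatase Ptprz1 (-7.17 ± 0.08) and the glutamate transporter Slc1a3 (-6.71 ± 0.15). Of 10 glial genes, 7 fell (7 adjusted over the list alone, median -3.39, adjusted p = 0.00171), such as Slc1a2 (-5.66 ± 0.05) and Aldh1l1 (-4.75 ± 0.47). Of 15 FGF and ERK target genes, 6 fell (5 adjusted over the list alone, median -1.81, adjusted p = 0.0385), among them Spry1 (-3.55 ± 0.20) and Dusp4 (-3.17 ± 0.36). Of 24 Hox genes, 3 rose (2 adjusted over the list alone, median 0.29, adjusted p = 0.0385). Mean log2(FPKM + 1) over the Hox list was 0 in NSC, so no Hox gene could fall. The upward direction of this list test was therefore fixed in advance. Median Hox levels stayed at FPKM 0.110 to 0.140 in the 3 lines. The adjusted p values with an estimated correlation were 0.0883 (neural stem cell), 0.358 (glia), 0.549 (FGF and ERK targets) and 0.346 (Hox). Among lists without a call, 6 of 10 neuron genes fell and 1 rose (adjusted p = 0.0783 for the list, the same counts adjusted over the list alone), Map2 by -5.04 ± 0.31 and Stmn2, a microtubule regulator, by 6.56 ± 0.49. In the imprinted list 10 of 24 genes rose and 3 fell (10 and 3 adjusted over the list alone, adjusted p = 0.0691 for the list), with Rian at 6.95 ± 0.60 and Slc38a4 at 6.28 ± 0.32. The glucose transporter gene Slc2a3 (4.83 ± 0.41) and the hexokinase gene Hk2 (3.54 ± 0.17) rose, with 3 of 16 glycolysis genes called in all (2 adjusted over the list alone). Over all 17011 genes tested, limma called 6639 at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold, 3112 higher and 3527 lower in NSC-CiPSC, and 10533 had an unadjusted p under 0.05. NSC is 1 library, so these calls assume that it varies like the lines.

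The comparison of IEC-CiPSC with IEC asks the same of the intestinal route. Pluripotency genes rose, while hepatic, pancreatic, mesenchymal and leukocyte transcripts of the IEC library fell. The largest rises were those of Dppa5a (5450 ± 252 against 0.230, log2 change 12.11 ± 0.29 SE, adjusted p = 3.06e-05), Pou5f1 (10.10 ± 0.11, adjusted p = 3.22e-06), Tdgf1 (9.52 ± 0.14, adjusted p = 6.01e-06), Nanog (8.91 ± 0.46, adjusted p = 0.000311), Trap1a, an X-linked gene (8.34 ± 0.05, adjusted p = 1.44e-06), and Mylpf (8.24 ± 0.11, adjusted p = 5.30e-06). Among the largest falls were those of Afp (-11.32 ± 0.10, adjusted p = 1.78e-06), Lyz2 (-11.28 ± 0.32, adjusted p = 5.12e-05) and Alb (-11.20 ± 0.09, adjusted p = 1.62e-06). Ctrb1, a chymotrypsinogen, and Ins2, an insulin gene, were at 1184 and 592 in IEC, were listed at 0 in both lines, and were called with adjusted p = 1.46e-05 and 1.44e-06.

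All 28 pluripotency genes rose (28 adjusted over the list alone, median 5.68, adjusted p = 2.16e-11), Sox2 among them (5.87 ± 0.06). Of 10 primed epiblast and early germ layer genes, 7 rose (7 adjusted over the list alone, median 1.77, adjusted p = 0.00818), including Zic2, listed at 0 in IEC and at 6.93 ± 0.346 in IEC-CiPSC, and Zic5 (2.95 ± 0.20). Of 10 tested genes of the 2-cell-like state 8 rose (8 adjusted over the list alone, median 2.50, adjusted p = 0.00209). Of 13 germline genes 10 rose (11 adjusted over the list alone, median 2.60, adjusted p = 0.000577), with Dnmt3l at 6.96 ± 0.76 and Piwil2, a piRNA pathway gene, at 3.85 ± 0.16. Of 16 glycolysis genes 12 rose (12 adjusted over the list alone, median 2.46, adjusted p = 0.000259), such as Slc2a3 (6.27 ± 0.44), Hk2 (4.06 ± 0.18) and Pgk1 (3.60 ± 0.53). In the DNA methylation machinery 6 of 9 genes rose and 1 fell (6 and 2 adjusted over the list alone, median 1.77, adjusted p = 0.0296), with Uhrf1 at 3.86 ± 0.12 and Tet1 at 3.68 ± 0.24. With an estimated correlation the adjusted p values were 0.0996 (pluripotency), 0.155 (primed epiblast, and also germline), 0.447 (2-cell-like), 0.493 (glycolysis) and 0.352 (DNA methylation machinery).

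All 20 fibroblast and mesenchyme genes fell (20 adjusted over the list alone, median -4.40, adjusted p = 1.23e-07), such as Col3a1 (-9.13 ± 0.29), Dcn (-8.82 ± 0.31) and Lum (-7.57 ± 0.06). All 10 smooth muscle genes fell (10 adjusted over the list alone, median -4.92, adjusted p = 0.000118), with Actg2 at -8.21 ± 0.29 and Myh11 at -7.22 ± 0.07. All 12 leukocyte genes fell (12 adjusted over the list alone, median -4.97, adjusted p = 3.27e-06), among them Fcer1g (-7.37 ± 0.22), C1qb (-6.62 ± 0.08) and Tyrobp, at 341 in IEC and listed at 0 in both lines. In the extraembryonic endoderm list, which holds Afp, 10 of 13 genes fell and 1 rose (11 and 1 adjusted over the list alone, median -3.83, adjusted p = 0.00141), with Ttr at -7.47 ± 0.10 and Dab2 at -5.95 ± 0.42. In the intestinal epithelium list 13 of 20 genes fell and 4 rose (15 and 4 adjusted over the list alone, median -1.69, adjusted p = 0.00443). The apolipoprotein gene Apoa1, also made by liver, fell by 7.89 on the log2 scale, and the fatty acid binding gene Fabp1 and the goblet cell gene Tff3 were at 109 and 82.9 in IEC and listed at 0 in both lines. The intestinal epithelium list shares Apoa1 and Apob with the liver list, whose median FPKM was 175 in IEC. Falls in this list need not be a loss of intestinal epithelium. In the imprinted list 14 of 24 genes fell and 2 rose (14 and 2 adjusted over the list alone, median -2.48, adjusted p = 0.00559), led, after Dcn, by H19 (-8.57 ± 0.24), Igf2 (-8.52 ± 0.43) and Dlk1 (-8.29 ± 0.46). In the Hox list 13 of 24 genes fell and 3 rose (13 and 3 adjusted over the list alone, median -2.49, adjusted p = 0.00868), with Hoxb2 at -3.97 ± 0.17 and Hoxa5 at -3.93 ± 0.18. Of 10 glial genes 3 fell (3 adjusted over the list alone, median -0.89, adjusted p = 0.0404), led by Pdgfra, also a mesenchymal gene (-5.02 ± 0.07). The adjusted p values with an estimated correlation were 0.103 (fibroblast and mesenchyme), 0.107 (leukocyte), 0.155 (smooth muscle, extraembryonic endoderm, intestinal epithelium and Hox), 0.235 (imprinted) and 0.408 (glia). Among lists without a call, 6 of 17 general epithelium genes rose and 3 fell (6 and 3 adjusted over the list alone), with a median of -0.53 but a mean of 0.17 and an upward test (adjusted p = 0.474). Krt8 (-3.47 ± 0.50) and Krt18 (-3.19 ± 0.53) were among those that fell. The Y-linked genes Ddx3y (-3.19 ± 0.31), Eif2s3y (-3.14 ± 0.57), Uty (-1.64 ± 0.39) and Kdm5d (-1.53 ± 0.26) fell, as did Xist (-3.84 ± 0.16), 5 of 6 genes in the sex chromosome list (5 adjusted over the list alone, adjusted p = 0.0910 for the list). The calls of Eif2s3y and Uty ended when 1 CiPSC line was left out, with adjusted p up to 0.0582 and 0.0945. In all, limma called 7714 of 17011 genes, 3252 higher and 4462 lower in IEC-CiPSC, and 11101 had an unadjusted p under 0.05. That balance depended on scaling, since after quantile normalization (genes changed, IEC_CiPSC against IEC) 4080 were higher and 3674 lower. IEC is also 1 library.

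The routes shared much of their change. Of the called genes, 1788 rose in both routes where 594.9 would be shared by independent lists of those sizes, 1818 fell in both where 925.1 would be shared, and 292 moved in opposite directions. The log2 changes of the routes had a Pearson correlation of 0.507 across genes, which are not independent replicates. A direct test of the difference between the routes called 5191 genes. Of these, 2989 had the more positive change in the neural route and 2202 in the intestinal route. In this test 8247 genes had an unadjusted p under 0.05. The difference between the lone NSC and IEC libraries enters this contrast in full, and it has no replicate check. Between the CiPSC groups themselves 735 genes were called.

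Closeness to ESC was described by the correlation of log2(FPKM + 1) across the genes tested. NSC and IEC had Pearson correlations with ESC of 0.719 and 0.619 (Spearman 0.691 and 0.583). The CiPSC lines had 0.948 ± 0.00254 (SD, n = 3, NSC-CiPSC) and 0.945 ± 0.00359 (SD, n = 2, IEC-CiPSC). The lines correlated with each other at 0.969 to 0.987 within NSC-CiPSC, at 0.989 within IEC-CiPSC, and at 0.940 to 0.960 between the origins. Genes are not replicates, so no p-value was computed.

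The comparisons of each CiPSC group with ESC ask what still separates the lines from embryonic stem cells. The strain differs with the group, since the ESC line is 129X1 x 129S1 and all other libraries are from C57BL/6J carrying a GOFGFP transgene crossed to ICR, so strain and cell origin cannot be told apart here. Most of the largest differences were in processed copies of ribosomal protein and ferritin genes, whose reads the counting may divide with their parent genes, and these are therefore uncertain. In NSC-CiPSC against ESC the largest rises were those of Rps18-ps3 (103.7 ± 25.4 against 0.226, log2 difference 6.39 ± 0.29 SE, adjusted p = 0.00340), Rps26-ps1 (670 ± 36.8 against 13.6, 5.52 ± 0.08, adjusted p = 7.30e-05), RP23-292F17.4 (5.41 ± 0.15, adjusted p = 0.000681), Rpsa-ps10 (4.98 ± 0.17, adjusted p = 0.00139) and Rpl7a-ps3 (4.90 ± 0.24, adjusted p = 0.00407), with Rpl7a-ps10 at 59.0 ± 2.71 and listed at 0 in ESC. The largest falls were those of Rps3a3 (0.434 ± 0.188 against 658, -8.85 ± 0.20, adjusted p = 0.000370), Rpl30-ps9 (-7.56 ± 0.47), Rpl30-ps10 (-6.94 ± 0.55), Ftl2 (-5.94 ± 0.26, adjusted p = 0.00308) and AA465934 (-4.67 ± 0.37), with Eif3s6-ps2 at 72.9 in ESC and listed at 0 in all 3 lines. In the pluripotency list the germline and naive-state gene Dppa3 was higher (26.4 ± 8.23 against 2.05, 3.12 ± 0.38, adjusted p = 0.0363) and Klf2 was lower (44.6 ± 6.31 against 127, -1.50 ± 0.22, adjusted p = 0.0497), 2 of 28 genes (1 higher and 3 lower adjusted over the list alone), and the list as a whole was lower (median -0.46, adjusted p = 0.0498). Zfp42 differed by -2.11 ± 0.32 (adjusted p = 0.0555). None of 10 tested genes of the 2-cell-like state was called over all genes (8 lower adjusted over the list alone), with a median of -1.17 and a downward list test (adjusted p = 0.000342). Both lists had adjusted p = 0.863 with an estimated correlation. The calls of Dppa3, Klf2, Rpl30-ps9, Rpl30-ps10, Eif3s6-ps2 and AA465934 ended when 1 CiPSC line was left out, with adjusted p up to 0.144. In all, limma called 478 genes, 161 higher and 317 lower in NSC-CiPSC, and 3758 had an unadjusted p under 0.05. The count was 720 without NSC-CiPSC line 1, 286 without line 2, 191 without line 3, and 187 and 192 without IEC-CiPSC lines 10 and 13, which enter through the shared estimate of the spread. It was 202 when only NSC-CiPSC and ESC were fitted.

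IEC-CiPSC had higher Ubd, a ubiquitin-like modifier gene (72.2 ± 0.544 against 0.136 in ESC, log2 difference 6.01 ± 0.60 SE, adjusted p = 0.0230), higher Cd3d and Cd3g, neighbouring genes of the T cell receptor complex (Cd3d 30.0 ± 0.109 against 0.0876, 4.83 ± 0.18, adjusted p = 0.00186; Cd3g 23.4 ± 1.97 and listed at 0 in ESC), and higher H2-Eb1, a class II histocompatibility gene (71.9 ± 1.80 against 3.33, 4.07 ± 0.34, adjusted p = 0.0166). Rps18-ps3 (6.22 ± 0.31, adjusted p = 0.00450) and Rpl35a-ps2 (4.43 ± 0.23, adjusted p = 0.00518) were the other large rises. The largest falls were those of Rps3a3 (-7.81 ± 0.21, adjusted p = 0.000772), Rpl30-ps9 (-7.56 ± 0.50), Rpl30-ps10 (-6.86 ± 0.58), Ftl2 (-6.60 ± 0.28), Eif3s6-ps2 (-5.44 ± 0.66) and Hist1h2af, one of several near-identical histone genes (-4.91 ± 0.29, adjusted p = 0.00707). In the 2-cell-like list 5 of 10 genes were lower (6 adjusted over the list alone, median -2.32, adjusted p = 2.84e-05), such as Zscan4f (12.6 ± 0.146 against 123, -3.20 ± 0.31) and Zscan4c (-3.06 ± 0.30). In the fibroblast and mesenchyme list 5 of 20 genes were higher (7 adjusted over the list alone, median 0.47, adjusted p = 0.000108), including Col1a1 (16.8 ± 0.276 against 1.36, 2.92 ± 0.32), Col1a2 (2.37 ± 0.23) and Sparc (1.39 ± 0.18). No glycolysis gene was called (0 of 16, also adjusted over the list alone) and the list test was upward (median 0.66, adjusted p = 0.0146). The Y-linked genes Eif2s3y, Ddx3y and Uty were lower by -4.49 ± 0.57, -3.79 ± 0.31 and -2.58 ± 0.39, 3 of 6 genes in the sex chromosome list (3 adjusted over the list alone, median -1.68, adjusted p = 0.00438). With an estimated correlation the adjusted p values were 0.726 (2-cell-like, and also sex chromosome), 0.417 (fibroblast and mesenchyme) and 0.928 (glycolysis). The estimate was 0.891 for glycolysis and 0.610 for 2-cell-like genes, so their list tests at the preset correlation are not reliable. Of the genes named for this comparison, the calls of Cd3d, Rps3a3, Ftl2 and Hist1h2af held with each CiPSC line left out, and those of the others ended in at least 1 such fit. In all, limma called 572 genes, 277 higher and 295 lower in IEC-CiPSC, and 4096 had an unadjusted p under 0.05. The count was 890, 377 and 209 without NSC-CiPSC lines 1, 2 and 3, 159 and 153 without IEC-CiPSC lines 10 and 13, and 123 when only IEC-CiPSC and ESC were fitted.

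**Figure D3:**
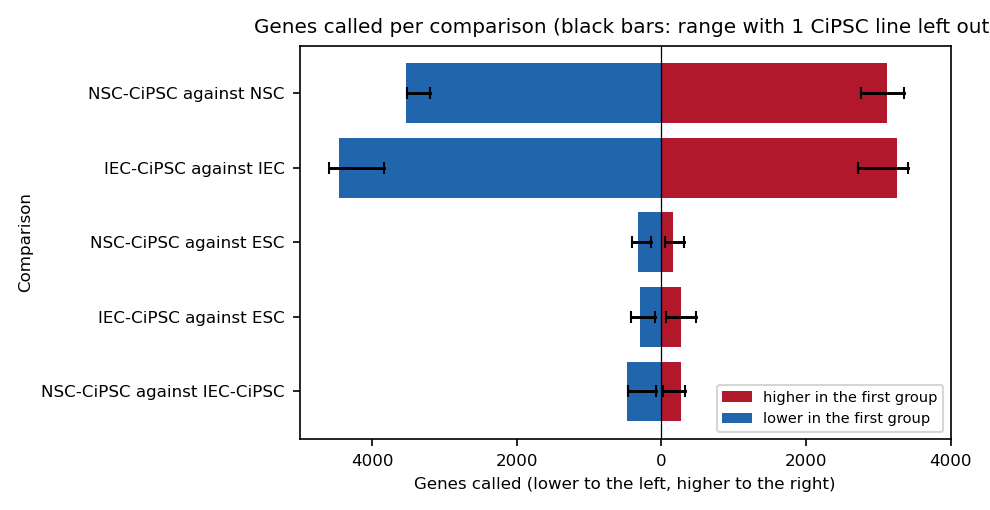
Number of genes called by limma (x axis) in each of 5 comparisons (y axis), with genes higher in the first group to the right and lower to the left; black bars span the counts with each CiPSC line left out in turn. The comparisons with the source cells call 6639 and 7714 genes and those with ESC call 478 and 572.

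Both CiPSC groups differed from ESC in many of the same genes. There were 50 genes higher in both, where 2.62 would be shared by independent lists of those sizes, and 178 lower in both, where 5.50 would be shared, and 0 moved in opposite directions. In 100 simulations of unchanged groups against a shared ESC library the mean number of genes shared was 0.01 and the highest was 1. These simulations gave ESC the same mean as the lines and the spread between lines of the same origin. Under that setting hardly any gene can be called, so a count near 0 was fixed in advance. It cannot tell a shared change of the lines from an effect of the 1 ESC library. The correlation of the log2 differences across genes was 0.623, against 0.706 in the simulations, and their covariance was 0.311, against 0.0749, a difference of 0.236. The single ESC library cannot be split, so part or all of the excess may come from that shared control. In all 228 were called the same way, a count that fell to 127, 105 and 103 without NSC-CiPSC line 3 and IEC-CiPSC lines 10 and 13, and to 93 when protein-coding genes without selenocysteine alone were tested, a restriction chosen after the data were examined.

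The 2 origins were also compared directly, 3 lines against 2. Higher in IEC-CiPSC were Xlr3a (120.3 ± 11.6 against 1.24 ± 1.49, NSC-CiPSC minus IEC-CiPSC -5.96 ± 0.60 SE, adjusted p = 0.0185), Xlr5a (-4.87 ± 0.29, adjusted p = 0.00752) and Xlr4a (-4.36 ± 0.25, adjusted p = 0.00725), X-linked lymphocyte-regulated genes that form a family of similar copies. Crxos1, a homeobox gene (71.0 ± 8.75 against 0.283 ± 0.259, -5.83 ± 0.23, adjusted p = 0.00398), Cd3d (-4.79 ± 0.13, adjusted p = 0.00153) and Cd3g (-4.42 ± 0.22, adjusted p = 0.00561) were higher in IEC-CiPSC as well. Higher in NSC-CiPSC were the ribosomal protein copies Rpl7a-ps10 (5.78 ± 0.13, adjusted p = 0.00148), Rps26-ps1 (5.40 ± 0.06, adjusted p = 0.000591), Rpsa-ps10 (5.21 ± 0.13, adjusted p = 0.00153), Rpsa-ps2 (5.20 ± 0.20, adjusted p = 0.00392) and Rpl7a-ps3 (4.97 ± 0.19, adjusted p = 0.00398), together with RP23-292F17.4 (5.40 ± 0.12, adjusted p = 0.00148). Among fibroblast and mesenchyme genes 7 of 20 were higher in IEC-CiPSC (8 adjusted over the list alone, median -0.61, adjusted p = 2.61e-05), such as Col1a1 (-2.27 ± 0.24) and Col1a2 (-2.23 ± 0.17). No glycolysis gene was called (0 of 16, also adjusted over the list alone) and the list test pointed to IEC-CiPSC (median -0.57, adjusted p = 0.00857). In the sex chromosome list 4 of 6 genes, all Y-linked, were higher in NSC-CiPSC (4 adjusted over the list alone, median 2.13, adjusted p = 0.0320), Ddx3y by 3.37 ± 0.23 and Eif2s3y by 4.79 ± 0.42. With an estimated correlation the adjusted p values were 0.323 (fibroblast and mesenchyme) and 0.873 (glycolysis, and also sex chromosome). For glycolysis the estimate was 0.891, so its list test at the preset correlation is not reliable.

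Among lists without a call, 5 of 10 tested genes of the 2-cell-like state were higher in NSC-CiPSC (5 adjusted over the list alone, adjusted p = 0.0635 for the list), Zscan4f by 2.00 ± 0.23. In the general epithelium list 4 of 17 genes were higher in NSC-CiPSC (4 higher and 2 lower adjusted over the list alone, adjusted p = 0.460 for the list), with Krt8 at 2.61 ± 0.37 and Krt18 at 2.53 ± 0.40. In the imprinted list 4 of 24 were higher and 1 lower in NSC-CiPSC (5 and 1 adjusted over the list alone, adjusted p = 0.113 for the list), Nnat at 2.93 ± 0.32, Phlda2 at 2.18 ± 0.17 and Plagl1 at -2.28 ± 0.11. The pluripotency genes Pou5f1 (-0.36 ± 0.09, adjusted p = 0.0825) and Nanog (-0.73 ± 0.34, adjusted p = 0.258) were not called. In all, limma called 735 genes, 265 higher in NSC-CiPSC and 470 higher in IEC-CiPSC, and 4894 had an unadjusted p under 0.05. The count was 356 and 142 without NSC-CiPSC lines 2 and 3, and 123 and 99 without IEC-CiPSC lines 10 and 13. Of the genes named here with a p-value, the calls of Crxos1, Cd3d and the ribosomal protein copies held with each line left out, and those of Xlr3a, Xlr4a, Xlr5a and Cd3g ended in at least 1 such fit. So did those of Col1a1, Col1a2, Ddx3y, Eif2s3y, Zscan4f, Krt8, Krt18, Nnat, Phlda2 and Plagl1.

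X-linked genes made up 3.92% of the genes tested and 19.5% of these calls, 143 of 735, of which 137 were higher in IEC-CiPSC; this summary was chosen after the values were seen. Over 293 X-linked protein-coding genes with mean FPKM of 5 or more in the pluripotent libraries, the median difference of IEC-CiPSC from NSC-CiPSC lay 1.02 above that of 8101 autosomal genes on the log2 scale, while the medians of the autosomes ran from -0.04 to 0.07. Against ESC the X-linked median of IEC-CiPSC lay 0.91 above the autosomal one, with autosomes from -0.31 to 0.11. Tested without X-linked and Y-linked genes, 540 genes were called between the origins.

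**Figure D4:**
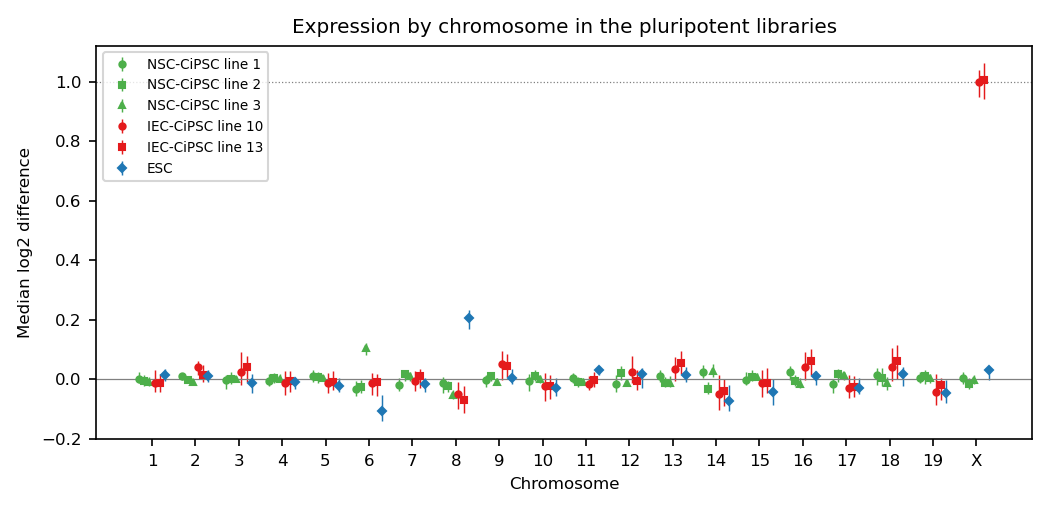
Median log2 difference of expressed protein-coding genes on each chromosome (x axis) in the 6 pluripotent libraries from the median of the NSC-CiPSC and ESC libraries, centred on the autosomes; lines are 95% bootstrap intervals over genes. Both IEC-CiPSC lines lie near 1.0 on X, and the other libraries within 0.05 of 0 there.

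Residual expression of source-cell genes was compared between the origins over 243 genes at least 8-fold higher in NSC than in both ESC and IEC, and 699 genes at least 8-fold higher in IEC than in both ESC and NSC. The median difference from ESC over the NSC genes was 0.04 ± 0.07 (SD, n = 3) in NSC-CiPSC and 0 in both IEC-CiPSC lines (exact two-sided permutation test, p = 0.7). Over the IEC genes it was 0 in all 5 lines (p = 1 by the exact permutation test). With 10 splits of 5 lines the smallest p this test can give is 0.1. Since these medians were at or near 0, the share of genes at least 2-fold above ESC was added after the data were examined. For the IEC genes it was 10.9% ± 0.303 in IEC-CiPSC and 6.91% ± 1.05 in NSC-CiPSC (exact two-sided permutation test, p = 0.1), and for the NSC genes 6.58% ± 1.16 and 5.62% ± 2.34 (exact p = 0.7). The direction for the NSC genes was not stable, since NSC-CiPSC minus IEC-CiPSC (residual source-cell expression, percent of NSC genes above ESC) went from -0.96 to 6.10 at pseudocount 0.1 and to 0.55 after quantile normalization. Between the origins, 39 of the 699 IEC genes (5.58%) were called higher in IEC-CiPSC, among them the matrix genes Col1a1, Col3a1 and Postn. The 39 also held processed copies of Rpl35a, whose levels are uncertain. Another 16 (2.29%) were called higher in NSC-CiPSC, such as H19, Krt18 and Des. Why these genes differed was not tested. Of all 17011 genes tested, 470 were called higher in IEC-CiPSC and 265 higher in NSC-CiPSC. These counts depend on the lines, since all calls between the origins went from 735 to 99 without IEC-CiPSC line 13, and the calls of Col1a1 and Postn ended in 3 and 5 of 7 alternatives (adjusted p up to 0.151 and 0.168). Of the NSC genes, 4 were called higher in NSC-CiPSC than in IEC-CiPSC (Slc1a3, Wscd1, Gatm and Gm23262) and 6 higher in IEC-CiPSC. A call between the origins need not be an excess over ESC, and Slc1a3 was at a mean FPKM of 6.08 in NSC-CiPSC and 6.08 in ESC. These genes were named after their values were seen.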

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

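The difference between the routes was a planned test, while the tests of clusters, of X chromosome number, of pseudogenes and of the IEC sample were chosen only after the result was seen. Values here are the change in the neural route minus that in the intestinal route on the log2 scale. Each value includes the difference between the lone NSC and IEC libraries, which has no replicate check. In all 5191 genes differed. Among pluripotency genes the difference was -1.84 for Pou5f1, -6.14 for Sox2, -2.01 for Esrrb, 3.29 for Klf4, -2.80 for Dppa5a and -1.10 for Tdgf1. The X-linked gene Trap1a had -1.80 and the heat shock gene Hspb1 5.69. Since Pou5f1 started from 2.02 in NSC and 0.0810 in IEC, and Sox2 from 171 and 3.00, differences in the source libraries enter these values directly.

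Neural genes changed more negatively in the neural route, with a median difference of -3.90 over the neural stem cell list, -1.76 over neuron genes and -2.72 over glia genes. The values were -2.51 for Nes, -2.75 for Pax6, -10.32 for Fabp7, -7.94 for Olig2, -8.77 for Ncan, -3.98 for Ednrb, -2.82 for Gpm6b, -5.34 for Ptprz1, -5.28 for Slc1a3, -4.95 for Slc1a2, -3.48 for Aldh1l1, -4.27 for Map2 and -1.30 for the ERK feedback gene Spry1. The primed epiblast and early germ layer list had -0.99, with -3.14 for Zic2 and -1.92 for Zic5, and the glycolysis list had -2.08, with -4.11 for Pgk1. Uhrf1 had -1.50.

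Genes of the IEC library changed more positively in the neural route. Median differences were 2.13 for intestinal epithelium, 2.78 for general epithelium, 4.76 for fibroblast and mesenchyme, 7.21 for smooth muscle, 6.23 for leukocyte, 4.11 for extraembryonic endoderm, 3.88 for imprinted, 1.66 for stress and immediate early and 2.52 for Hox genes. With an estimated correlation none of the 14 lists kept an adjusted p under 0.05. Epithelial genes had 3.81 (Epcam), 3.70 (Cdh1), 2.31 (Cldn4), 8.30 (Krt18) and 8.42 (Krt8). Mesenchymal and muscle genes had 7.77 (Col1a1), 9.37 (Col3a1), 9.01 (Dcn), 7.57 (Lum), 4.08 (Pdgfra), 8.76 (Actg2) and 7.24 (Myh11). Leukocyte genes had 10.97 (Lyz2), 8.42 (Tyrobp), 7.63 (Fcer1g) and 6.62 (C1qb). Secreted and endodermal genes had 11.23 (Afp), 11.17 (Alb), 10.33 (Ctrb1), 9.21 (Ins2), 8.11 (Apoa1), 6.78 (Fabp1), 6.39 (Tff3), 7.38 (Ttr), 5.66 (Dab2) and 4.11 (Gata6). Imprinted genes had 9.13 (Meg3), 8.51 (Rian), 5.41 (Slc38a4), 12.31 (H19), 10.30 (Igf2) and 8.44 (Dlk1). The remaining values were 1.97 (Zscan4f), 1.78 (Zscan4c), 4.17 (Hoxb2), 4.20 (Hoxa5), 1.28 (Xist), 3.42 (Ddx3y) and 3.65 (Eif2s3y).

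X-linked genes were about 2.02-fold higher in IEC-CiPSC than in NSC-CiPSC. The median of X-linked genes was taken relative to that of autosomal genes, so a scaling factor per library largely cancels. That the difference was 0.98 after quantile normalization is therefore little evidence on scaling. Base composition and transcript length are unlikely causes, since they predicted a difference of 0.00774. A few clusters are unlikely too, as 100% of the 15 windows tested were raised by 0.5 or more. The number of active X chromosomes in the IEC-CiPSC lines stays open, because the lowest difference over 8 pairs of libraries, 0.92, restates the pattern. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were called lower in IEC-CiPSC than in NSC-CiPSC (4 of 6 sex chromosome genes, each call ending in 2 or 3 of 7 alternatives). In both IEC-CiPSC lines 0 of these 6 genes reached FPKM 1, against 4 or 5 in every other library. The IEC library held both Xist and Y-linked transcripts. A difference in the sex of the lines or their source embryos, or loss of Y with gain of X, stays open and untested.

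Pseudogenes of all kinds, many of them copies of ribosomal protein genes, made up 5.59% of genes tested, and 24.9% and 19.4% of the calls of NSC-CiPSC and IEC-CiPSC against ESC. Reads assigned to a copy or to its parent may explain part of this, since the parents of called copies that could be paired by name moved the other way by a median of -0.32 (bootstrap SE 0.08, 18 parents). Genomic DNA in 1 library would raise pseudogenes on the same side, but at least 38.7% were on the minority side in each of the 3 comparisons of pluripotent groups. The strain of the ESC line is unlikely to be the whole cause, as 75 pseudogenes were called between the origins, which share a strain label. They made up 10.2% of those calls, a lower share than in the comparisons with ESC, so strain may still be part of the cause. Sequence variants between lines remain possible, since one strain in the cross is outbred and reads were not analysed here.

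The IEC library held transcripts of several organs. Of 5 cell class lists other than epithelium, 3 lay beyond the 99th percentile of 10000 matched random lists against NSC (fibroblast and mesenchyme, smooth muscle and leukocyte). This count cannot decide whether there were several cell types in 1 sample, since epithelium was taken out of it after its outcome was known. The intestinal and general epithelium lists also lay beyond that percentile, with median IEC minus NSC differences of 1.94 and 2.93 on the log2 scale. In IEC 12 of 12 macrophage, 18 of 18 liver and 13 of 14 exocrine pancreas genes reached FPKM 10. Those lists were written after such genes had been seen. Among endothelium and enteric neural crest genes 0 of 12 and 2 of 10 did so. Fetal liver that carries blood is unlikely to be the source of Afp and Alb, since the erythroid list had a median FPKM of 0.0579. Low erythroid transcripts cannot exclude liver cells carried over without blood, so a hepatic source stays open. A wrong label or a sample of another tissue was not tested and stays possible. With 1 IEC library, every change against IEC carries this composition.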

How the results depend on the processing

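Alternatives for marked entries, protein-coding genes, X and Y, and the share of source genes were chosen after seeing the data, and the causes of the shifts were not tested. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. By adjusted p alone the counts were 738 for genes changed, NSC_CiPSC against ESC, 1622 for genes changed, NSC_CiPSC against IEC_CiPSC, 6092 for genes changed the same way in both routes and 351 for genes changed the same way against ESC in both origins. With protein-coding genes without selenocysteine only, NSC-CiPSC against ESC gave 232, IEC-CiPSC against ESC 369 and both origins 93. With only the groups compared in the fit they gave 202, 123 and 60. Leaving out 1 line gave 187 to 720 for NSC-CiPSC against ESC, 153 to 890 for IEC-CiPSC against ESC, 99 to 789 between the origins and 103 to 332 for genes changed the same way against ESC in both origins. The count of genes differing between NSC and IEC was 2276 at 4-fold. The correlation with ESC, NSC, was 0.674 at pseudocount 0.1 and 0.803 without a filter on low values. In the same settings the correlation with ESC, IEC, was 0.537 and 0.743 (0.626 after quantile normalization), the correlation with ESC, NSC_CiPSC, 0.930 and 0.9625, and the correlation with ESC, IEC_CiPSC, 0.929 and 0.960. The difference in the percent of NSC genes above ESC changed sign, from -0.96 to 6.10 at pseudocount 0.1 and 0.55 after quantile normalization. Tests of the planned gene lists called 0 lists in each of 5 comparisons with an estimated correlation. For NSC-CiPSC against ESC they called 1 at pseudocount 0.1, and 1 to 2 with 1 line left out, and between the origins 1 to 4. Quantile normalization moved the median change of all genes from -0.03 to 0.15 in the intestinal route. Depth of 8.85 to 10.2 M fragments limits genes with low levels. The lone NSC, IEC and ESC libraries could not be left out.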

Other observations

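Lefty1, Lefty2 and Fabp3 were chosen after their values were seen and were higher in the lines than in the 1 ESC library, but their calls in NSC-CiPSC against ESC ended in 3, 4 and 3 of 7 alternatives (adjusted p up to 0.0780, 0.130 and 0.0888). Lefty1 was at 37.9 to 59.8 in NSC-CiPSC and 30.3 and 34.0 in IEC-CiPSC against 2.70 in ESC. Lefty2 was at 29.6 to 49.7, 97.8 and 102, against 5.40 in ESC. Fabp3 was at 468 to 824 in NSC-CiPSC, 344 and 289 in IEC-CiPSC and 33.7 in ESC. The de novo methyltransferase Dnmt3a was at 13.6 and 14.9 in IEC-CiPSC, 43.6 to 89.5 in NSC-CiPSC and 42.8 in ESC, and Dnmt3b at 25.3 and 31.5, 51.1 to 106.5, and 50.4. Their cofactor Dnmt3l was at 192 and 199, 87.5 to 257, and 301. Of 9 DNA methylation machinery genes, 0 were called between the origins (1 higher in NSC-CiPSC adjusted over the list alone). In IEC-CiPSC against ESC 0 of 9 were called, also adjusted over the list alone.

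In the lists added after the data were seen, exocrine pancreas (13 of 13), endocrine pancreas (9 of 10), liver (18 of 18), stomach and pancreatic mesenchyme (7 of 8) and macrophage genes (12 of 12) fell from IEC to IEC-CiPSC, with 13, 9, 18, 8 and 12 adjusted over the list alone. The estimated-correlation adjusted p values were 0.0214, 0.0277, 0.0214, 0.0441 and 0.0214, but their members were chosen after such genes had been seen. The Xlr list was also written after the data were seen, so its p-values do not test a pattern fixed in advance. In the Xlr cluster, X-linked genes of similar sequence, 9 of 9 were higher in IEC-CiPSC than in NSC-CiPSC (9 adjusted over the list alone, adjusted p = 2.77e-11, and adjusted p = 0.279 with an estimated correlation), and 8 of 9 were lower in NSC-CiPSC than in ESC (9 adjusted over the list alone, adjusted p = 1.04e-10, and adjusted p = 0.299 with an estimated correlation).

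The median of chromosome 8 in ESC lay 0.21 above the median of the NSC-CiPSC and ESC libraries. That of chromosome 6 in ESC lay at -0.11, and that of chromosome 6 in NSC-CiPSC line 3 at 0.10. This reference includes ESC itself, which shrinks its values. Directly against ESC, the lowest autosome median was -0.32 for NSC-CiPSC and -0.31 for IEC-CiPSC. A chromosome shift in the 1 ESC library enters both comparisons with ESC.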
